A study of Caenorhabditis elegans with 4 samples.

How the data were processed

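Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on wild-type Caenorhabditis elegans of strain N2 at the L3 larval stage, in mixed populations of males and hermaphrodites. The antibody was an affinity-purified rabbit polyclonal against RPC-1, the largest subunit of RNA polymerase III, the polymerase that transcribes tRNA genes, 5S rRNA genes and other short non-coding RNA genes. The labels give 4 libraries, 2 of RPC-1 ChIP DNA and 2 of input DNA, each numbered as replicate 1 or replicate 2. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, worms were synchronised by bleaching and hatching, grown in liquid culture and frozen, extract was immunoprecipitated in the presence of sarkosyl, and indexed single-end libraries were amplified by PCR and sequenced on Illumina instruments. Nothing in the labels says whether the 2 ChIP libraries came from separate worm cultures, so differences between them may be technical.

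The values analysed are 3 peak lists, 1 for each ChIP library and 1 for the whole series. Per the submitters' processing notes, BWA and the genome build ce10 were used; the versions are not given in the sources used here. Per the file headers, coordinates are on WormBase WS220, 1-based. Per the files themselves, the replicate lists were called with MACS and the series-wide list with MACS v2. Whether the series-wide list was called on pooled reads, how the input libraries entered, which duplicate or mapping filters were applied and which threshold was set are not given in the sources used here. The deposited score of each peak is the authors' own value from the caller, and its scale is not stated. Scores of the replicate lists began just above 50 and reached 3233, and 174 peaks of replicate 1 and 594 of replicate 2 shared the value 3100, so that these peaks cannot be ranked among themselves. Scores of the series-wide list ran on another scale. Within a list, scores were used to rank and split peaks and to compare groups of peaks by their medians. Scores of 1-to-1 pairs of replicate peaks were compared by Spearman's rho, with Pearson's r on the deposited values beside it, and pairs at the tied score entered both. Read counts and library depths are unknown, so no interval that needs a read depth could be given. Intervals on shares of peaks are exact Clopper-Pearson 95% intervals, which cover counting error only and treat peaks as independent, although neighbouring peaks are not. Beside a count of 0, the upper limit that 3 counts of the total would give is also stated, which is an approximate one-sided 95% limit and so lies below the two-sided interval's.

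No genome sequence or annotation of WS220 was used here. The gene table at hand was that of assembly WBcel235, another build, and coordinates were not compared between the builds. No peak was therefore assigned to a gene, and the planned comparisons that need such an assignment (peaks at tRNA genes and at other RNA classes, tRNA genes with a peak, peaks away from Pol III genes, the B box promoter motif, and the protein-coding comparison lists) were not made. The gene table served only for the number of genes of each class on each chromosome and for the order of neighbouring genes. The classes were those that the table names as tRNA, tRNA pseudogene, snoRNA, snRNA, miRNA, other non-coding RNA (ncRNA) and protein-coding gene, and the 5S rRNA genes by their symbol.

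Peaks of the mitochondrial chromosome were reported separately and left out of every comparison. Replicate overlap was the share of peaks of one list that overlapped a peak of the other by at least 1 bp. It was tested by placing the peaks of the other list at random 1000 times, each keeping its width and chromosome, with a one-sided p whose smallest possible value was 0.000999. The end of the last peak on a chromosome in any list stood for the chromosome's length, which gave 99.86 Mb for the 6 nuclear chromosomes together. Peaks per chromosome were tested against this length with an exact binomial test, two-sided, with Benjamini-Hochberg adjustment over the 6 chromosomes. Peaks per chromosome were related to gene number by Spearman's rho and Pearson's r with exact permutation of the chromosomes. Tests of scores used 100000 permutations, two-sided, whose smallest possible p was 1e-05. Shares were compared with Fisher's exact test, two-sided. The binomial and Fisher's exact tests also treat single peaks as independent, so their p values can be too small where peaks lie near each other. Chromosome results led with the series-wide list, and each replicate's own list was the leave-one-out alternative.

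The overlap test was run first on simulated lists of 1671 and 1451 peaks. With 836 and 1337 planted shared peaks, 869 and 1346 peaks overlapped, against means of 45.3 and 34.5 over 200 random placements (one-sided permutation p = 0.00498 for both, the smallest possible). In 20 simulations with 0 planted peaks, 37 to 60 peaks overlapped, against a random mean of 51.7, and none gave a permutation p under 0.05 (lowest 0.129). Planted peaks were slightly widened copies of peaks in the other list, so their overlap was certain. All other simulated peaks were placed by the random rule of the test itself. The simulations thus check the computation, and not whether that rule suits peaks that lie near each other. Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Designs of the main comparisons, alternatives and the rule for naming were fixed before the data were examined. With no assignment of peaks to genes, that rule names the 10 highest-scoring series-wide peaks found in both replicates and the 3 highest-scoring unshared peaks of each replicate, by position. Ties in score were broken by chromosome order and lowest coordinate, a choice the rule made for another of its parts. Alternatives were the peaks at or above the median score of each list, an overlap of at least 50% of the shorter peak, peak centres within 200 bp, random placement over the whole genome, each replicate's list alone, and series-wide peaks found in both replicates. Merging of peaks up to 1 kb apart, counting runs of neighbouring tRNA genes once, leaving out chromosome X, leaving out peaks at the tied score, and the alternatives for neighbouring peaks and for positions along chromosomes, with peaks up to 2 kb apart merged into groups for the latter, were added after the data had been seen. Some tests in the Results were not part of the designs fixed beforehand. They are those of the X share by score and by replicate support, and of the scores of shared against unshared peaks. Pearson's r across chromosomes and the relations with chromosome length and with gene classes other than tRNA were also not part of them.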

Results

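Binding of RPC-1, the largest subunit of RNA polymerase III (Pol III), was mapped across the genome of wild-type L3 larvae by ChIP-seq. Of the 4 libraries, 2 were RPC-1 ChIP and 2 were input. Peak lists were analysed for the 2 ChIP libraries and for the series as a whole, and values of the input libraries were not analysed here. Replicate 1 had 1671 peaks, all on the nuclear chromosomes. Replicate 2 had 1452 peaks, 1 of them on the mitochondrial chromosome. The series-wide list held 1651 peaks, 3 of them mitochondrial. Nuclear peaks covered 962 kb in replicate 1, 2076 kb in replicate 2 and 649 kb in the series-wide list, or 0.964%, 2.08% and 0.65% of the length of the nuclear chromosomes.

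The first comparison was between the 2 ChIP libraries, and asked whether RPC-1 was found at the same places in both. Most regions were. Of the 1671 peaks of replicate 1, 1429 (85.5%, 95% interval 83.7 to 87.2) overlapped a peak of replicate 2, and of the 1451 nuclear peaks of replicate 2, 1262 (87.0%, 85.1 to 88.7) overlapped a peak of replicate 1. Random placement gave means of 51.7 and 51.9 overlapping peaks and at most 78 and 75 (permutation p = 0.000999 in both directions, the smallest that 1000 placements can give). The 836 peaks of replicate 1 at or above its median score were all found in replicate 2 (100.0%, 99.56 to 100.0), which allows an unshared share of up to 0.359% by the one-sided limit of 3 counts. Of the 726 peaks of replicate 2 at or above its median score, 722 (99.4%, 98.6 to 99.9) were found in replicate 1. Below the median score the shared shares were 71.0% (67.8 to 74.1) in replicate 1 and 74.5% (71.1 to 77.6) in replicate 2.

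Unshared peaks scored lower than shared ones in each library. The median score in replicate 1 was 74.9 for the 242 unshared peaks and 1347 for the shared ones. In replicate 2 it was 154 for the 189 unshared peaks and 2964 for the shared ones. Both differences gave p = 1e-05 in a permutation test of the medians, the smallest possible value. The 3 highest-scoring peaks of replicate 1 that were missing from replicate 2 lay at X 12990673 to 12991110 (score 656), II 5547514 to 5547912 (score 490) and I 15060219 to 15071351 (score 487). The last of these spanned 11133 bp and was the last peak of replicate 1 on chromosome I; the last peak of replicate 2 there ended at 14800988. In the gene order of WBcel235, the ribosomal RNA genes rrn-1.1, rrn-2.1, rrn-3.1 and rrn-1.2, which RNA polymerase I transcribes, are among the last genes of chromosome I, with 3 genes after rrn-1.2. No peak was matched to them by coordinate. The 3 highest-scoring unshared peaks of replicate 2 each had the tied score of 3100 and lay at II 4640814 to 4645295, III 1016956 to 1021012 and V 264598 to 267683. All of these unshared regions except that at the end of chromosome I overlapped a series-wide peak.

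Shared peaks kept their rank between the libraries. Over the 1116 pairs in which 1 peak of each library overlapped only the other, Spearman's rho of the scores was 0.902 and Pearson's r was 0.891 (permutation p = 1e-05 for each, across peaks, which are not independent replicates). Without the 2 peaks farthest from the median score of replicate 1, r was 0.892. In these pairs, 171 peaks of replicate 1 and 509 of replicate 2 had the tied score of 3100 or more. Among peaks at or above the median score of each list rho was 0.417 over 631 pairs.

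The same regions were drawn wider in replicate 2. The median width was 482 bp (quartiles 353.5 and 654) in replicate 1 and 1257 bp (quartiles 1090 and 1422.5) in replicate 2, and 335 bp (quartiles 262 and 436.5) in the series-wide list. In 1114 of the 1116 pairs the peak of replicate 2 was the wider, with a median ratio of 2.35 (quartiles 2.02 and 2.91). No peak of replicate 1 overlapped more than 1 peak of replicate 2, whereas 146 peaks of replicate 2 overlapped 2 or more peaks of replicate 1. The widest nuclear peak of the series-wide list lay at V 7916874 to 7924997 (8124 bp). Replicate 2 had a peak of 8659 bp there, at V 7916639 to 7925297. Another wide region of replicate 2, V 17119489 to 17132593, contained a peak of replicate 1 of 6922 bp at V 17119758 to 17126679; the score of the region was 250 in replicate 2, and that of the contained peak was 3223 in replicate 1. The series-wide list had 7 separate peaks in this region, with scores from 1.58 to 17.96.

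**Figure D1:**
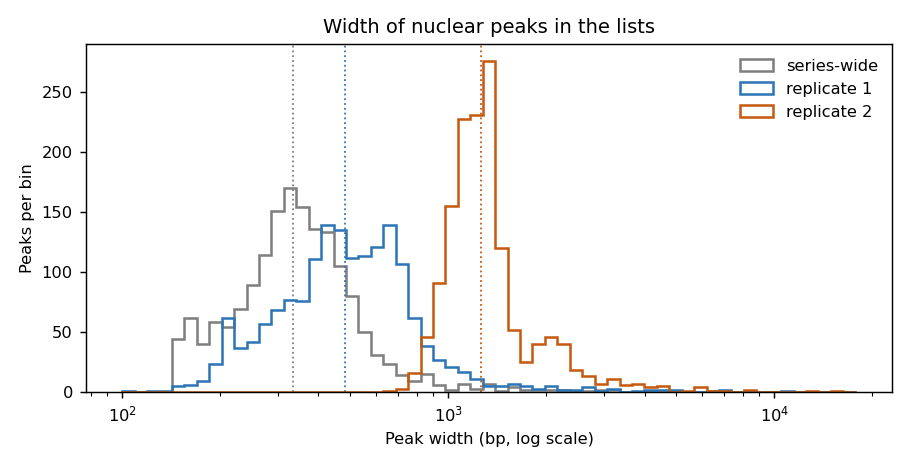
Histograms of the width of nuclear peaks (x axis, bp, log scale) in the series-wide list and in each ChIP replicate (y axis, peaks per bin), with dotted lines at the medians. The medians were 335 bp in the series-wide list, 482 bp in replicate 1 and 1257 bp in replicate 2, whose narrowest peak was 678 bp wide.

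The series-wide list was next compared with the replicate lists. The series has no ChIP libraries other than these 2, so the lists are not independent, and overlap between them is not separate support for a peak. Of the 1648 nuclear peaks of the series-wide list, 1398 (84.8%, 83.0 to 86.5) overlapped a peak of both replicates, 46 only of replicate 1, 130 only of replicate 2 and 74 of neither. The median score was 90.3 for peaks found in both replicates, 9.02 and 8.80 for those found in only replicate 1 or only replicate 2, and 4.88 for those found in neither. All 824 peaks at or above its median score were found in both replicates (100.0%, 99.55 to 100.0), which allows a share without such support of up to 0.364% by the same one-sided limit. Conversely, 96 of the 1429 peaks of replicate 1 that replicate 2 shared (6.72%, 5.48 to 8.14) overlapped no series-wide peak; their median score was 91.9, against 1457 for the others.

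The highest series-wide score, 173.72, was reached by 23 peaks, all found in both replicates. Of these, 13 lay on chromosome X, 4 on II, 3 on IV, 2 on V, 1 on III and 0 on I. Because ties were broken by coordinate, the 10 peaks named by the rule are all autosomal. On chromosome II they lay at 5292108 to 5292584, 11960552 to 11961109, 13834219 to 13835032 and 14804151 to 14804906. On chromosome III the peak lay at 5080607 to 5081116. On chromosome IV the peaks lay at 5966909 to 5967387, 14013606 to 14014025 and 15932980 to 15933521, and on chromosome V at 9317966 to 9318390 and 9503295 to 9503764. In replicate 2 each of these regions had a score of 3100. In replicate 1, 7 of them had a score of 3100, and the regions at II 5292108, IV 14013606 and V 9317966 had scores of 3023, 3022 and 3030.

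**Figure D2:**
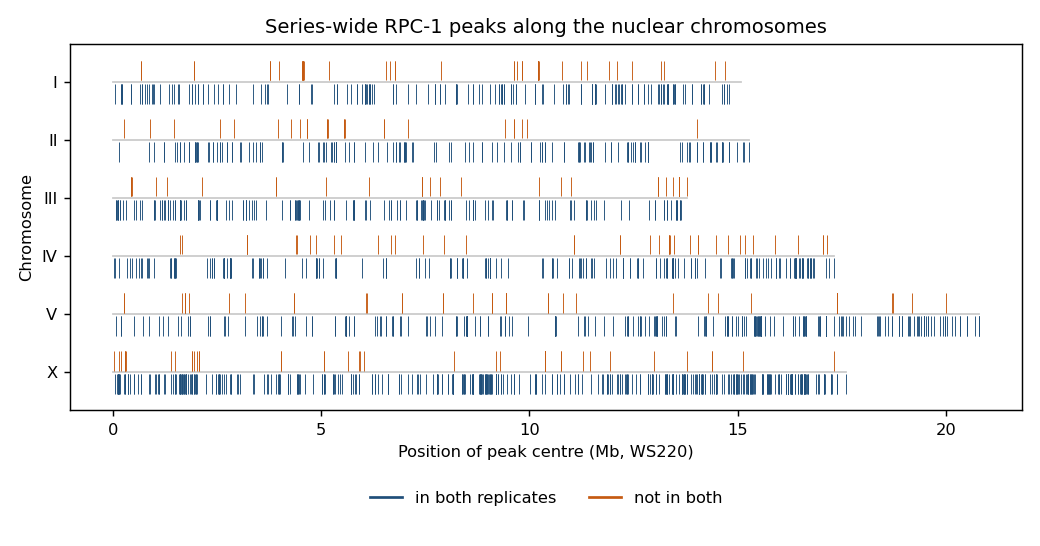
Positions of the 1648 nuclear series-wide peaks along the 6 nuclear chromosomes (x axis, Mb on WS220). Below each chromosome line stand the 1398 peaks found in both replicates, and above it the 250 others; X carries 466 peaks.

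Another comparison asked how RPC-1 peaks were spread over the chromosomes, since tRNA genes, the main genes of Pol III, are unevenly spread in this species. Chromosome X carried the most peaks. It held 466 of the 1648 nuclear series-wide peaks (28.3%, 26.1 to 30.5) on 17.6% of the length, 1.60 times its share by length (exact binomial test, adjusted p = 1.33e-25). Its density was 26.5 peaks per Mb, while the 5 autosomes ranged from 12.3 peaks per Mb on II to 15.7 on III. In the same exact test, chromosomes II (187 peaks, 0.742 times the share by length, adjusted p = 1.31e-05) and V (297 peaks, 0.865 times, adjusted p = 0.00955) held fewer peaks than their length would give. Chromosomes I (226 peaks, 0.909 times), III (216 peaks, 0.95 times) and IV (256 peaks, 0.896 times) did not pass an adjusted threshold of 0.05 in the exact test, with adjusted p values of 0.146, 0.432 and 0.0823. For chromosome I this depended on the list: it held fewer peaks than its share in replicate 2 (0.836 times, adjusted p = 0.0165), among series-wide peaks found in both replicates (0.834 times, adjusted p = 0.0133) or at or above the median score (0.788 times, adjusted p = 0.0147) and after peaks up to 1 kb apart were merged (0.859 times, adjusted p = 0.0461), and did not pass in replicate 1 (0.876 times, exact test, adjusted p = 0.0511). The X share was 27.9% (25.8 to 30.1) in replicate 1 and 28.5% (26.1 to 30.9) in replicate 2, a mean of 28.2% ± 0.407 (SD, n = 2).

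The number of peaks per chromosome followed the number of tRNA genes. WBcel235 lists 612 nuclear tRNA genes, of which X carries 276 (45.1%), V 78, IV 71, I 66, III 64 and II 57. The order of the 6 chromosomes by peaks was exactly their order by tRNA genes (Spearman's rho = 1.00, exact permutation p = 0.00278, adjusted p = 0.0222 over 8 relations). Pearson's r was 0.956 (exact permutation p = 0.00139, adjusted p = 0.0111), and 1.00 after rounding over the remaining 4 chromosomes without X and II, the farthest from the median. Without X alone, rho was 1.00 and r was 0.996 over the 5 autosomes (exact permutation p = 0.0167 and 0.00833). Over these autosomes, peaks rose from 187 on II (57 tRNA genes) to 297 on V (78 tRNA genes). X, with 276 tRNA genes, had 466 peaks, fewer than that slope would give. The autosomal r thus does not speak for a single linear relation over all 6 chromosomes. Relations other than that with tRNA genes were not computed without X alone. In both replicate lists rho with tRNA genes over the 6 chromosomes was also 1.00.

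None of the other 7 relations reached the adjusted threshold. Spearman's coefficient was 0.771 for chromosome length (adjusted p = 0.412), 0.657 for other ncRNA genes (adjusted p = 0.467), 0.429 for miRNA genes (adjusted p = 0.670) and 0.348 for tRNA pseudogenes (adjusted p = 0.681), by exact permutation. It was 0.029 for protein-coding genes, -0.029 for snRNA genes and -0.543 for snoRNA genes, small RNAs that guide rRNA modification (exact permutation, adjusted p = 1.00, 1.00 and 0.594). Pearson's r for other ncRNA genes was 0.953 (exact permutation p = 0.0181, adjusted p = 0.0724), but it fell to -0.049 without V and X. For snoRNA genes r was -0.885 (exact permutation p = 0.0278, adjusted p = 0.0741) and -0.661 without I and X. Whether these differed from the relation with tRNA genes was not tested.

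**Figure D3:**
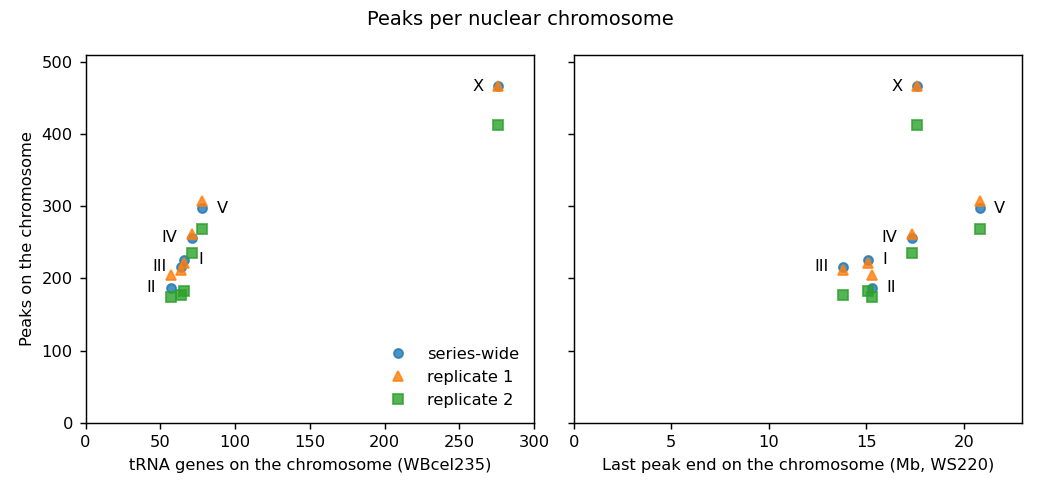
Number of peaks on each nuclear chromosome (y axis) against its number of tRNA genes in WBcel235 (left x axis) and the end of its last peak in Mb on WS220 (right x axis), for the series-wide list and each replicate. Labels stand beside the series-wide points; the order by peaks, from II with 187 to X with 466, is the order by tRNA genes, from 57 to 276.

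Chromosome X was most prominent among the strongest peaks. When the series-wide peaks were cut by score into 4 sets of 412, X held 170 peaks of the highest-scoring set (41.3%, 36.5 to 46.2). In the other sets, from the lowest score up, X held 22.1%, 26.2% and 23.5%. The highest-scoring set differed from the other peaks (Fisher's exact test, odds ratio 2.23, p = 5.55e-11). Peaks at or above the median score (32.4%, 29.2 to 35.7) differed from those below it (24.2%, 21.3 to 27.2) by Fisher's exact test (odds ratio 1.51, p = 0.000243). They contain the highest-scoring set, so this is not separate support, and the third set alone (23.5%) was not above the second (26.2%). Both tests took single peaks as units, although neighbouring peaks are not independent, and were not repeated on merged peaks. For comparison, X holds 45.1% (41.1 to 49.1) of tRNA genes and 13.7% of protein-coding genes. In replicate 1, X held 98 of the 206 peaks at or above the tied score (47.6%, 40.6 to 54.6). In replicate 2, where 611 peaks reached that score, X held 206 of them (33.7%, 30.0 to 37.6).

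Peaks not found in both libraries were spread differently. X held 45 of the 242 unshared peaks of replicate 1 (18.6%, 13.9 to 24.1) and 29.5% of its shared peaks. In replicate 2 these shares were 19.0% (36 of 189 peaks, 13.7 to 25.4) and 29.9%. Of the 250 series-wide peaks that were not found in both replicates, 74 of them in neither, 46 lay on X (18.4%, 13.8 to 23.8). Of those found in both, 30.0% did. Each of the 3 differences passed Fisher's exact test (odds ratios of 1.83, 1.81 and 1.91, adjusted p = 0.000536, 0.00182 and 0.000388), and the 3 lists are not independent of each other. Score was not held equal in these tests, which also took single peaks as units and were not repeated on merged peaks. All 242 unshared peaks of replicate 1 and 185 of the 189 of replicate 2 scored below the median of their list. Below the median, X held 24.55% (21.67 to 27.62) of all peaks in replicate 1 and 25.1% (21.98 to 28.43) in replicate 2. These shares include the unshared peaks, so they lie closer to the unshared shares than those of shared peaks below the median would.

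**Figure D4:**
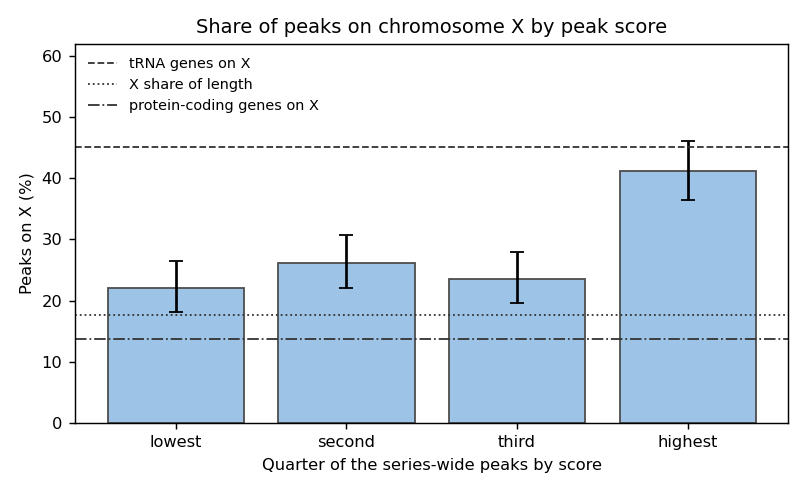
Share of series-wide peaks that lie on chromosome X (y axis, %) in 4 sets of equal size by score (x axis), with exact 95% intervals as error bars, which cover counting error only. Lines mark the X share of tRNA genes (45.1%), of chromosome length (17.6%) and of protein-coding genes (13.7%); the highest-scoring set stands at 41.3% and the others between 22.1% and 26.2%.

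The mitochondrial chromosome, which a separate mitochondrial polymerase transcribes, was called nearly whole in 1 library. Replicate 2 had a single peak from position 16 to 13256 (13241 bp), and replicate 1 had none. The score of that peak was 1487, in a list whose lowest score was 50.74 and whose median was 2294. The series-wide list had peaks from 11 to 6646, 6794 to 10474 and 10750 to 13249, with scores of 16.2, 9.71 and 11.5, below that list's median of 69.0. Mitochondrial peaks entered no comparison.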

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

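Of the 42 alternative values from settings chosen before the data were examined, 37 kept the direction of their result and its side of the 0.05 threshold, or stayed within the interval, as did 16 of the 18 from settings added after the data had been seen. The settings reuse the same peaks, so these values are not independent checks. Random placement over the whole genome, for example, leaves the observed overlap unchanged by construction. The share of peaks on chromosome I, 0.909 times its share by length, passed the threshold at 0.788 to 0.859 times in 4 of 5 alternatives, and the cause was not tested. The fullest window of 1 Mb passed on 2 chromosomes instead of 4 once peaks up to 2 kb apart were merged into groups. The share of series-wide peaks found in both replicates, 84.8%, moved to 94.1% when only peaks at or above the median score of each list were used and to 60.7% when peak centres had to lie within 200 bp; it was 84.6% with an overlap of at least 50% of the shorter peak. Under the 200 bp rule the shared share was also lower between the replicates, 66.3% of replicate 1 and 76.2% of replicate 2, and the cause was not tested. The rank agreement of scores fell from 0.902 to 0.417 among peaks at or above the median score, where by construction the range is narrower and 533 of the 631 peaks of replicate 2 share the tied score or exceed it. Without peaks at the tied score it was 0.855. With 1 ChIP list left out, the X share was between 27.9% and 28.5% and the rank relation with tRNA genes was 1.00. This relation was 0.899 for series-wide peaks at or above the median score (exact permutation p = 0.0278) and 0.943 for peaks found in both replicates, for merged peaks and for runs of neighbouring tRNA genes (exact permutation p = 0.0167 each). Unlike the adjusted p of the main relation, these p values were not adjusted over the 8 relations. They entered the count above unadjusted, and whether they would pass after adjustment was not computed. No paired analysis was possible because only the ChIP libraries had peak lists, so the shared replicate numbers of input and ChIP could not enter a fit. Leaving out a replicate gave no value where the replicates were compared with each other or with the series-wide list. Alternatives for results that need genes or sequence on WS220 were not run. Read depth, which limits how many weak peaks a library yields, is unknown here.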

Other observations

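All tests in this part were chosen after the results they bear on had been seen, except the share of unshared peaks with a neighbour in the other library. RPC-1 peaks lay near each other more often than random placement gave, to an extent that differed between the lists. Of the 1648 nuclear series-wide peaks, 658 (39.9%, 37.5 to 42.3) had another peak within 2 kb, against a mean of 134.6 (8.17%) and at most 182 when peaks were placed at random on their chromosomes. The share was 30.9% (28.7 to 33.2, random mean 8.77%) in replicate 1 and 21.3% (19.2 to 23.5, random mean 10.14%) in replicate 2, where 146 peaks overlapped 2 or more peaks of replicate 1. After series-wide peaks up to 1 kb apart were merged, 8.70% of the 1311 left had a neighbour from 1 to 2 kb away, against a random mean of 2.71%. Each of these 4 comparisons gave a one-sided permutation p of 0.000999, the smallest possible. Series-wide, neighbours were less frequent among peaks at or above the median score (33.9%) than among those below it (46.0%; Fisher's exact test, odds ratio 0.601, p = 6.15e-07). Replicate 2 gave the same direction (18.04% and 24.6%, Fisher's exact test, odds ratio 0.677, p = 0.00258), while in replicate 1 the difference had the opposite sign and did not pass (32.2% and 29.7%, Fisher's exact test, odds ratio 1.123, p = 0.290).

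Peaks were also uneven along some chromosomes. The middle 33.3% of the length of chromosome IV held 23.05% of its 256 series-wide peaks (18.03 to 28.7) and that of X 27.5% of its 466 (23.5 to 31.8), below an even spread (exact binomial test, adjusted p = 0.00251 and 0.0206). In the same exact test, both replicate lists gave the same direction on IV (24.5% in replicate 1 and 22.6% in replicate 2, adjusted p = 0.00737 and 0.00118) and on X (25.1% and 24.5%, adjusted p = 0.000891 and 0.000642). On V the share passed the threshold of the exact test in replicate 2 (26.02%, adjusted p = 0.0230) and not in replicate 1 (27.7%, adjusted p = 0.0787) or the series-wide list (28.6%, adjusted p = 0.193). With peaks up to 2 kb apart merged into groups, the shares on IV and X stayed below an even spread in each list (exact binomial test, adjusted p from 0.00483 to 0.0169), and V passed in none. The fullest windows of 1 Mb were X 16 to 17 Mb with 47 series-wide peaks (42 in replicate 1 and 34 in replicate 2), IV 16 to 17 Mb with 31 (31 and 25), V 17 to 18 Mb with 31 (17 and 22) and III 13 to 14 Mb with 30 (18 and 12). Against the fullest window of the chromosome in random placements of single peaks, each passed the 0.05 threshold (permutation test, adjusted p = 0.009, 0.006, 0.009 and 0.009), and those of I and II did not pass it (adjusted p = 0.362 and 0.0971). That test takes neighbouring peaks as independent, and 7 of the peaks on V lie in the region that replicate 2 drew as 1 peak. With groups placed instead of peaks, which could then fall closer than 2 kb, the fullest windows that passed were IV 16 to 17 Mb with 24 groups and X 1 to 2 Mb with 37 (permutation test, adjusted p = 0.045 and 0.03). In the replicate lists the window on X passed with 43 and 41 groups (permutation test, adjusted p = 0.012 and 0.006), while that on IV did not (22 and 21 groups, adjusted p = 0.336 and 0.137).

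The excess of peaks on X was weighed against 3 explanations. If each of the 612 annotated tRNA genes had 1 peak, 1036 of the 1648 peaks (62.9%) would lie elsewhere, and X would keep 10.79 of its 26.5 peaks per Mb, within the 8.52 to 11.03 of the autosomes. The same subtraction left X within the autosomes in replicate 1 (10.8, with 9.69 to 11.01) and replicate 2 (7.78, with 7.66 to 9.47). It overshot among peaks at or above the median score, where X had 267 peaks and so fewer than its 276 tRNA genes (X at -0.51, autosomes 2.12 to 3.48). It also overshot in merged peaks (5.34, with 6.35 to 8.14) unless neighbouring tRNA genes were merged too (7.61, with 6.88 to 8.49). On the autosomes, the series-wide peaks left by the subtraction still followed the order by tRNA genes, from 130 on II to 219 on V. Totals per chromosome do not show which genes have a peak. A peak at most tRNA genes stays a candidate explanation for the excess on X that a match of peaks to WS220 genes could test directly. Merging peaks up to 1 kb apart cut X from 466 to 370 peaks and lowered each autosome too, so splitting of sites as such is not excluded. The tables argue against it as the source of the excess on X, since the X share stayed at 28.2% (25.8 to 30.7, with 17.6% of the length). They leave open whether X was over-represented in the libraries as a whole: X held 18.6% of the unshared peaks of replicate 1 (13.9 to 24.1), an interval that includes its share of the length, but these peaks are also the weak ones, and the input libraries were not analysed here.

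Both libraries belong to 1 group, and the labels do not say whether they came from separate worm cultures. A difference between cultures could therefore not be tested, and the design names no factor behind the greater width of replicate 2. Joining of neighbouring peaks does not account for it, because peaks that overlapped 1 to 1 still differed by a median ratio of 2.349 (lower quartile 2.02). The lowest-scoring 25% of peaks in replicate 2 had a median width of 1016 bp (lower quartile 925.5). That lies above the upper quartile of 779 bp in the highest-scoring 25% of replicate 1. The 5th percentile of width was 905 bp in replicate 2 and 214 bp in replicate 1. Whether signal was stronger in replicate 2 cannot be told from this. The scale of the scores is not stated and library depths are unknown, so a score need not mean the same strength in both libraries. Fragment length and the caller's settings are not recorded in the sources used here and were not tested, so these stay open too.

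Peaks found in 1 replicate only were seldom edges of a peak that the other library placed beside them: 3.72% of those of replicate 1 (upper limit 6.94) and 6.88% of those of replicate 2 had a peak of the other library within 1 kb. Whether they lay near the authors' threshold depended on the library. In replicate 1, whose lowest score was 50.06, 69.01% of the unshared peaks (62.8 to 74.8) scored at most 2 times the lowest score. In replicate 2, whose lowest score was 50.74, the share was 33.9% (27.2 to 41.1), and 3 unshared peaks had the tied score of 3100 or more. At limits of 1.5 and 3 times the shares were 50.0% and 81.4% in replicate 1 and 21.2% and 49.7% in replicate 2. The threshold is thus not shown to account for them, and whether they are background or weakly bound regions stays open, since library depths are unknown.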
